A study of Mus musculus with 60 samples.

How the data were processed

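Per the labels, sorted cells were taken by repeated sorting through a gate on live CD45+Tcrb+CD4+Thy1.1+ cells, and whole tissue entered with 2 ng of RNA. Polyadenylated RNA was primed with oligo(dT), amplified by Smart-seq2 and tagged with Nextera XT. The deposited values are counts per gene, which the authors made by aligning reads to mm10 with STAR 2.7.3a and counting them with featureCounts, per the submitters' processing notes. The annotation release, strand setting and handling of reads with several matches are not given in the sources used here. The table holds 55011 genes, 44386 of them with a count, and totals run from 3007241 to 9673342 counts per library. All 60 libraries were used.

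Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each comparison was filtered with filterByExpr, normalized by TMM and fitted with the robust quasi-likelihood model. The 3 Treg groups, the 3 groups of the CL experiment and the 4 groups of each interaction were fitted together, and other comparisons held their own libraries. The quasi-likelihood F test was adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE is the size of the log2 fold change over the square root of F. CPM values are group means with SD over libraries. Undetected groups were given a floor of 3 counts over the group.

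Fixed lists, 27 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and at least 3 tested members, adjusted over the lists of a comparison. The test was repeated with a correlation estimated per list. Members called were counted over all genes and adjusted over the list alone. Some lists share genes, and list genes were chosen without regard to these data. Called sets were followed only between comparisons without a common library.

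Named genes always include Foxp3 and Il2ra, with Pparg in Treg cells and Ucp1 in tissue. To these come up to 10 higher and 10 lower genes by size of log2 fold change, with an adjusted p under 0.05, at least 5 CPM in the higher group and ranges that do not overlap. Predicted, ribosomal and variable-segment genes were left out. Each list adds up to 4 called members by p, or its 2 most expressed if none was called, and counts of 5 or fewer are named in full, and the text gives a part of them; results for some genes are not reported here. Positions come from GENCODE M21, which held 402 of the 405 named genes.

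The procedure was tested on simulated counts with 200 changed genes in each of the 13 comparisons. With edgeR 17 to 70% of genes changed by log2 of 1 and 74 to 98% of those changed by 2 were recovered (40 and 79% for Treg BAT against SAT), and 4.03 to 12.2% of calls were false. With DESeq2 1.42.0 false calls were 7.60 to 21.7%. Replicates were checked for near copies, and all 67 pairs differed beyond counting noise (chi-square per degree of freedom 7.02 to 37.6 over genes with at least 20 counts). Alternatives were DESeq2, RLE factors, no filter, a replicate block, other sets of groups per fit, other controls for the cold libraries and each library left out in turn. Raw reads were not analysed here.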

Results

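Gene expression was measured by RNA sequencing in 60 mouse libraries that fall into 19 groups. Of these, 8 libraries came from regulatory T (Treg) cells sorted from 8-week-old Foxp3-Thy1.1 reporter males, 2 from interscapular brown adipose tissue (BAT), 3 from subcutaneous adipose tissue (SAT) and 3 from spleen. The other 52 came from whole tissue, 38 from BAT and 14 from SAT. In DTR+ mice Foxp3-expressing cells carry the diphtheria toxin receptor, so that the toxin can remove Treg cells, and DTR- mice lack the transgene. The groups named D4 had 4 libraries per genotype in BAT and in SAT, and those named D3 had 3 per genotype in each tissue. Whether D3 and D4 are days after toxin or names of experiments is not stated. In BAT, 3 further groups of 3 libraries covered DTR- mice given PBS, DTR- mice given CL and DTR+ mice given CL, where CL is taken to be CL-316243, an agonist of the beta-3 adrenergic receptor. A pair of groups of 3 compared wild-type mice given PC61, an antibody against the CD25 chain of the IL-2 receptor, or isotype. Another pair of 3 compared DTR+ mice given an antibody against interferon gamma (IFNg) or isotype. The last group held 3 BAT libraries from mice kept at 4 degrees, whose titles say WT and whose genotype labels say DTR-. Because the labels do not say that replicates are separate animals, p-values measure the spread between these samples, which may be technical. The fits, lists and rules for naming genes were fixed before the data were examined. Coordinates are those of mm10.

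Sorted Treg cells were compared first, to ask what sets Treg cells of fat apart from those of spleen. Foxp3 itself (chromosome X, 7573644 to 7595245) stood at 387 ± 39.5 CPM (counts scaled to a common library size, mean and SD, n = 3) in spleen, 398 ± 12.5 (n = 2) in BAT and 402 ± 35.8 (n = 3) in SAT. The log2 fold change of fat over spleen was 0.05 ± 0.09 (SE, edgeR adjusted p = 0.79). Il2ra, the CD25 chain, fell by 0.54 ± 0.10 on the log2 scale (adjusted p = 0.0041). Over the whole transcriptome, 1009 genes were higher and 730 lower in fat Treg cells of 13847 tested. Rora (chromosome 9, 68653786 to 69388246), a nuclear receptor of tissue lymphocytes, rose by 2.26 ± 0.13 (adjusted p = 7.5e-07), from 61.6 ± 4.35 CPM in spleen to 320 ± 5.02 in BAT and 271 ± 50.5 in SAT. Pparg (chromosome 6, 115360951 to 115490399), the nuclear receptor that marks Treg cells of visceral fat, rose by 3.57 ± 0.48 (adjusted p = 0.00045) from 1.57 ± 1.21 CPM to 17.6 ± 6.06 and 19.8 ± 3.96.

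Of 28 genes on the list of tissue Treg markers, 24 rose and 0 fell over all genes tested (24 rose and 1 fell adjusted over the list alone). Their mean log2 fold change was 2.20 (camera adjusted p = 4.1e-28 and 0.038 with an estimated correlation). Besides Rora and Pparg these included Lmna, which encodes lamin A (4.68 ± 0.30), and the chemokine receptor Ccr4 (1.43 ± 0.11). The growth factor Areg (6.15 ± 0.50) and the IL-33 receptor gene Il1rl1 (3.00 ± 0.31), picked from this list after their values were seen, also rose. On the list of general Treg genes 8 of 18 rose and 5 fell, 8 and 7 adjusted over the list alone, and the list as a whole did not move (mean 0.05, camera adjusted p = 0.36). Within it the costimulatory receptors Icos (1.11 ± 0.10) and Ctla4 (1.25 ± 0.13) rose, and the folate receptor family gene Izumo1r fell by 1.47 ± 0.14. Genes of naive and recirculating T cells went down, 10 of 16 lower and 1 higher (11 and 2 adjusted over the list alone, mean -0.87, camera adjusted p = 1.4e-06 and 0.20 with an estimated correlation). They included the chromatin organizer Satb1, which fell by 1.44 ± 0.17, and the transcription factors Tcf7, which fell by 0.88 ± 0.13, and Lef1, which fell by 0.55 ± 0.09.

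Immediate-early and stress genes made up most of the largest increases. Of 20 listed members 17 rose and 1 fell (18 and 1 adjusted over the list alone, mean 4.29, median 3.43, also with the members undetected in spleen set to their bound, camera adjusted p = 1.1e-26 and 0.018 with an estimated correlation). Fosb (chromosome 7, 19302696 to 19310051) went from 0.364 ± 0.316 CPM in spleen to 151 ± 16.8 in BAT and 199 ± 62.0 in SAT (8.84 ± 0.42). Fos (7.97 ± 0.57), Jun (5.78 ± 0.27), Junb (3.39 ± 0.17) and the mRNA-decay factor Zfp36 (2.58 ± 0.16) rose with it, as did the chemokine Cxcl2 (8.37 ± 0.65). Several genes had no count in the 3 spleen libraries, and their folds are lower bounds against 3 counts over the spleen group. The heat shock gene Hspa1a was at least 2023-fold higher in BAT Treg cells and at least 362-fold higher in SAT Treg cells, although reads that match both it and its near-identical neighbor Hspa1b (7.76 ± 0.72) cannot be assigned with certainty. The stress factor Atf3 was at least 271-fold and 165-fold higher.

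Effector genes also rose, 9 of 23 on the T and NK cell list with 2 lower (10 and 3 adjusted over the list alone). The mean was 1.81, or 1.64 with a median of 1.60 when 4 members undetected in a group are set to their bound or left out where they have none (camera adjusted p = 8.5e-05 and 0.20 with an estimated correlation). Examples were the T-bet gene Tbx21 (3.37 ± 0.33), the cytotoxic granule gene Nkg7 (2.80 ± 0.23), the chemokine Ccl5 (3.10 ± 0.30) and Ifng itself (4.05 ± 0.44). Ifng stood at 1.99 ± 0.993 CPM in spleen against 29.4 ± 4.52 in BAT and 38.3 ± 19.1 in SAT. Cell-cycle genes were higher in 12 of 25 cases with 0 lower (14 and 0 adjusted over the list alone, mean 0.92, camera adjusted p = 1.8e-08 and 0.33 with an estimated correlation). Among them were Mki67 (1.22 ± 0.21) and the cyclin Ccnb2 (1.96 ± 0.28). The IFNg response list showed no common direction (3 of 40 higher and 8 lower, 4 and 9 adjusted over the list alone, mean 0.06, median -0.12, camera downward with adjusted p = 0.23). The type I interferon list (2 of 23 higher, 3 lower, the same adjusted over the list alone, mean -0.17) also did not move together (camera adjusted p = 0.23).

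Markers of other cells were followed in the sorted libraries. The iron exporter Slc40a1 fell by 7.80 ± 0.62, the complement genes C1qa and C1qb by 4.50 ± 0.73 and 4.91 ± 0.91 and the CSF1 receptor gene Csf1r by 3.69 ± 0.79. Of the general macrophage list 1 of 14 rose, the chemokine receptor Ccr2 (3.62 ± 0.26), which tissue Treg cells also express, and 5 fell (2 and 7 adjusted over the list alone). The mean was -1.38, or -1.11 with a median of -0.51 at the bound (camera adjusted p = 0.14). Lists of B cell, endothelial, fibroblast, adipocyte, muscle, oxidative phosphorylation and mitochondrially encoded genes did not move (camera adjusted p from 0.090 to 0.47). The count of genes rests on the 3 spleen libraries: without replicate 1, 2 or 3 it was 1158, 914 or 1056 in place of 1739.

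Treg cells of the 2 fat depots were then compared with each other in the same fit. No gene passed the threshold of 13847 tested (0 by edgeR at an adjusted p under 0.05, 1231 at an unadjusted p under 0.05, and 42 higher and 48 lower in BAT by DESeq2). Foxp3 (-0.01 ± 0.12, adjusted p = 0.99), Il2ra (-0.25 ± 0.13, adjusted p = 0.60) and Pparg (-0.17 ± 0.48, adjusted p = 0.96) were close in both depots. The naive T cell list was higher in BAT as a group (mean 0.59, camera adjusted p = 1.9e-09 and 0.37 with an estimated correlation). Of 16 members 0 passed over all genes and 2 adjusted over the list alone. B cell markers behaved alike as a group (mean 1.28, 0 of 10 members over all genes, 1 adjusted over the list alone, camera adjusted p = 6.5e-06 and 0.48 with an estimated correlation). The cell-cycle list (mean 0.37, 0 of 25 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.0067 and 0.81 with an estimated correlation) was weaker. It lost its call in 3 of the 8 fits with 1 library left out, at adjusted p = 0.59 and a mean of -0.21 without BAT replicate 2. The other lists did not differ (camera adjusted p of 0.11 or more). Leaving out SAT replicate 1 or 2 raised the count of genes from 0 to 14 or 1.

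Whole tissue was examined next, for what differs in fat between toxin-treated DTR+ and DTR- mice. Foxp3 transcripts were too few to measure a loss of Treg cells. BAT of the D4 groups had 2, 0, 0 and 0 Foxp3 counts in the 4 DTR- libraries and 0 in each of the 4 DTR+ libraries. SAT had 2, 0, 29 and 0 against 0, 3, 0 and 0. In D3 SAT the sum over 3 libraries was 8 in DTR- and 6 in DTR+ (0.397 and 0.284 CPM), and groups of later BAT comparisons held 0 to 7. A count of 0 allows up to 3 counts of the total, and these limits cover counting error only. In D4 BAT, 1021 genes were higher and 861 lower in DTR+ than in DTR- tissue of 11695 tested (n = 4 and 4). Ucp1 (chromosome 8, 83290352 to 83298452), the uncoupling protein of brown fat heat production, fell from 5447 ± 688 to 2574 ± 194 CPM, by 1.08 ± 0.09 on the log2 scale (adjusted p = 3.2e-06). The interferon-inducible GTPase Iigp1 (chromosome 18, 60376027 to 60392634) rose from 16.4 ± 9.05 to 350 ± 155 CPM (4.39 ± 0.55, adjusted p = 0.0036). The monocyte attractant Ccl2 (chromosome 11, 82035571 to 82037453) went from 1.63 ± 1.82 to 54.9 ± 37.5 CPM (4.95 ± 0.84).

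Nearly all interferon response genes rose. Of 42 IFNg response genes 39 rose and 0 fell, the same adjusted over the list alone (mean 2.15, camera adjusted p = 1.7e-39 and 0.061 with an estimated correlation). Among them were the MHC class I transactivator Nlrc5 (2.81 ± 0.23) and the peptide transporter Tap2 (1.31 ± 0.12). All 22 type I interferon genes rose, also adjusted over the list alone (mean 2.31, camera adjusted p = 5.1e-22 and 0.091 with an estimated correlation). Examples were Irf7 (3.00 ± 0.25) and the antiviral gene Rsad2 (2.17 ± 0.19). The nucleic acid sensor Zbp1 (4.47 ± 0.45), the chemokine Cxcl10 (4.87 ± 0.87) and Gbp10 (5.57 ± 0.70) were among the largest increases.

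Immune cell genes also rose. All 8 T and NK genes high enough in either group to test rose (mean 2.84, camera adjusted p = 7.1e-08 and 0.061 with an estimated correlation). Examples were Lck (3.24 ± 0.50) and Cd8b1 (4.19 ± 0.66), each below 11 CPM in DTR+ tissue. Of 19 macrophage and monocyte genes 14 rose and 1 fell (17 and 1 adjusted over the list alone, mean 2.06, camera adjusted p = 2.4e-12 and 0.091 with an estimated correlation). These included Plac8 (4.19 ± 0.52) and the Fc receptor gene Fcgr1 (3.20 ± 0.48). The macrophage elastase Mmp12 (chromosome 9, 7344381 to 7369499, 5.47 ± 0.75), osteopontin (Spp1, 4.56 ± 1.08) and Capg (2.76 ± 0.39) also rose. Of 7 Treg list genes Capg alone moved, also adjusted over the list alone (camera adjusted p = 0.27 for the list). All 3 neutrophil genes were higher (mean 2.18, camera adjusted p = 0.0039 and 0.13 with an estimated correlation; S100a8, 2.46 ± 0.49). Cell-cycle genes rose in 15 of 20 cases (17 higher and 1 lower adjusted over the list alone, mean 1.65, camera adjusted p = 6.8e-10 and 0.061 with an estimated correlation). Examples were Mcm3 (1.53 ± 0.21) and Ccna2 (3.39 ± 0.47). Immediate-early genes were higher in 8 of 16 cases (10 adjusted over the list alone, mean 1.64, camera adjusted p = 4.6e-09 and 0.14 with an estimated correlation), with Atf3 (3.12 ± 0.53). cAMP response genes rose in 3 of 12, the same adjusted over the list alone (mean 0.89, camera adjusted p = 0.00024 and 0.14 with an estimated correlation), with Pde4b (1.05 ± 0.22) and Ppargc1a (0.73 ± 0.19). Matrix genes rose in 8 of 20 (11 adjusted over the list alone, mean 0.54, camera adjusted p = 8.9e-05 and 0.15 with an estimated correlation), with Timp1 (3.58 ± 0.48).

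Metabolic genes fell together. Of 21 de novo lipogenesis genes 13 fell and 0 rose (17 and 0 adjusted over the list alone, mean -1.01, camera adjusted p = 1.0e-14 and 0.091 with an estimated correlation). ATP citrate lyase (Acly, chromosome 11, 100476353 to 100528000) fell by 2.29 ± 0.54, the acyltransferase Agpat2 by 1.35 ± 0.10 and Thrsp by 1.25 ± 0.12. Of 79 nuclear-encoded oxidative phosphorylation genes 67 fell and 0 rose (74 and 0 adjusted over the list alone, mean -0.37, camera adjusted p = 6.8e-32 and 0.097 with an estimated correlation). Fatty acid oxidation genes fell in 17 of 23 cases (20 lower and 1 higher adjusted over the list alone, mean -0.43, camera adjusted p = 4.6e-13 and 0.061 with an estimated correlation). Of 13 mitochondrially encoded genes 6 fell, also adjusted over the list alone (mean -0.35, camera adjusted p = 0.00018 and 0.13 with an estimated correlation; mt-Nd1, by 0.69 ± 0.10). Of 23 thermogenic genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, mean -0.28, camera adjusted p = 6.3e-05 and 0.11 with an estimated correlation). Besides Ucp1 the elongase Elovl3 fell by 1.83 ± 0.21 and Letmd1 by 0.69 ± 0.09. General adipocyte markers did not move as a list (1 of 15 higher and 3 lower, the same adjusted over the list alone, mean -0.09, camera adjusted p = 0.15).

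Several lists in D4 BAT were close to the threshold. Lipolysis genes (2 of 14 lower and 1 higher, 4 and 1 adjusted over the list alone, mean -0.13, camera adjusted p = 0.048 and 0.13 with an estimated correlation) lost their call without DTR+ replicate 2 (adjusted p = 0.061) or 3 (0.085). Red cell genes (2 of 5 lower, 3 adjusted over the list alone, mean -0.36, camera adjusted p = 0.016 and 0.28 with an estimated correlation) lost it without DTR+ replicate 3 (0.054), with Hba-a2, which shares sequence with Hba-a1, down by 0.52 ± 0.16. Stress genes of the unfolded protein response (5 of 14 higher and 1 lower, the same adjusted over the list alone, mean 0.47, camera adjusted p = 0.048 and 0.13 with an estimated correlation) lost it without any 1 of 6 libraries. These were DTR- replicates 1 to 4 (0.054, 0.055, 0.079 and 0.081) and DTR+ replicates 1 (0.060) and 3 (0.085). Members that rose included Atf4 (0.80 ± 0.11) and Gdf15 (4.25 ± 0.71). Endothelial, type 2 immune, Schwann cell and muscle lists did not move (camera adjusted p from 0.16 to 0.90). Ighm, the only B cell gene tested, fell by 1.18 ± 0.27.

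In SAT of the D4 mice far fewer genes passed. In DTR+ 38 were higher and 2 lower of 12728 tested (n = 4 and 4), against 73 and 13 by DESeq2. The increases were led by Iigp1, from 74.4 ± 17.0 to 464 ± 86.2 CPM (2.64 ± 0.17, adjusted p = 6.4e-06), Igtp (2.39 ± 0.16), Irgm2 (1.80 ± 0.14), whose gene overlaps Igtp on the same strand, and Gbp10 (2.90 ± 0.28). The decreases were those of the immunoglobulin gene Ighm (chromosome 12, 113418558 to 113422730), by 1.29 ± 0.21 from 444 ± 131 to 181 ± 38.5 CPM, and the protease Adamts10, by 1.04 ± 0.19. IFNg response genes rose in 19 of 45 cases (35 higher and 1 lower adjusted over the list alone, mean 0.96, camera adjusted p = 6.1e-54 and 0.020 with an estimated correlation). Type I interferon genes rose in 5 of 23 (14 adjusted over the list alone, mean 0.65, camera adjusted p = 3.8e-22 and 0.090 with an estimated correlation). Among them were Bst2 (0.86 ± 0.11), Xaf1 (0.86 ± 0.15), Oasl2 (0.92 ± 0.16) and Ifit3 (0.99 ± 0.18), which has a near copy in Ifit3b. Of 3 B cell genes 1 fell (2 adjusted over the list alone, mean -2.68, camera adjusted p = 0.00040 and 0.16 with an estimated correlation). Ucp1, at 31.6 ± 36.4 and 3.16 ± 2.30 CPM, did not pass the test (adjusted p = 0.64). The count of genes was 23 without DTR- replicate 4 and 24 without DTR+ replicate 2. DTR- replicate 3 held 393 CPM of T and NK genes against 65.9 to 92.0 in the other DTR- libraries, and DTR+ replicate 3 held 3305 CPM of muscle genes. Without both, a choice made after seeing the data, 49 genes were higher and 22 lower.

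Some other lists in D4 SAT passed camera with 0 members called over all genes, and most rested on single libraries. Neutrophil genes (1 of 5 higher adjusted over the list alone, mean 0.90, adjusted p = 0.019 and 0.16 with an estimated correlation) lost the call without DTR+ replicate 4 (0.057), and fatty acid oxidation genes (mean -0.17, adjusted p = 0.0050 and 0.79 with an estimated correlation) without DTR- replicate 3 (0.19). Lipogenesis genes (mean -0.21, adjusted p = 0.028 and 0.79 with an estimated correlation) lost it without DTR- replicate 2 (0.18) or 3 (0.46) or DTR+ replicate 1 (0.24) or 2 (0.41). Immediate-early genes (mean 0.19, adjusted p = 0.022 and 0.31 with an estimated correlation) lost it without DTR- replicate 2 (0.18) or DTR+ replicate 2 (0.21). Unfolded protein response genes (mean 0.30, adjusted p = 0.028 and 0.40 with an estimated correlation) lost it without DTR- replicate 3 (0.19) or DTR+ replicate 2 (0.070) or 3 (0.056). Mitochondrially encoded genes (mean -0.23, adjusted p = 0.022 and 0.79 with an estimated correlation) did so without DTR- replicate 3 (0.14) or 4 (0.26) or DTR+ replicate 2 (0.17) or 4 (0.057). Except for neutrophil genes, none of these lists had a member past the threshold adjusted over the list alone. The other 16 lists had 0 members called, also adjusted over the list alone, and camera adjusted p from 0.065 to 0.99, though T and NK genes passed without DTR- replicate 3 (mean 0.77, adjusted p = 2.7e-07).

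Whether the DTR+ effect differed between the depots was tested as the interaction of genotype and tissue. The log2 change in BAT lay above that in SAT for 413 genes and below it for 142 of 13502 tested. Of the IFNg response list 16 of 46 genes responded more in BAT and 0 less (33 and 0 adjusted over the list alone, mean 1.27, camera adjusted p = 6.3e-21 and 0.10 with an estimated correlation). Examples were Zbp1 (3.21 ± 0.48) and Irf1 (1.60 ± 0.26). Of the type I list 14 of 23 genes responded more (21 adjusted over the list alone, mean 1.61, camera adjusted p = 8.1e-18 and 0.10 with an estimated correlation), Irf7 among them (2.42 ± 0.32). Cell-cycle genes did likewise (7 of 25, 19 adjusted over the list alone, mean 1.93, mean 1.75 without the 1 member undetected in a group, camera adjusted p = 4.9e-13 and 0.010 with an estimated correlation), with Ccna2 (3.43 ± 0.57) and Kif11 (5.36 ± 0.95). So did macrophage genes (8 of 20 more and 1 less, Cd163, 15 and 1 adjusted over the list alone, mean 2.00, camera adjusted p = 6.6e-12 and 0.15 with an estimated correlation), with Ccl2 (4.55 ± 0.90) and Itgax (4.22 ± 0.87), and T and NK genes (4 of 22, 14 adjusted over the list alone, mean 2.79, camera adjusted p = 1.5e-07 and 0.17 with an estimated correlation), with Il2rb (2.25 ± 0.57). The interaction was negative for lipogenesis genes (2 of 21, 5 adjusted over the list alone, mean -0.82, camera adjusted p = 8.7e-09 and 0.18 with an estimated correlation), with Agpat2 at -1.05 ± 0.26. It was also negative for oxidative phosphorylation genes (8 of 80, 62 adjusted over the list alone, mean -0.43, camera adjusted p = 6.4e-26 and 0.18 with an estimated correlation), with Ndufv3 at -0.66 ± 0.15. For Ucp1 it was 2.18 ± 1.16 (adjusted p = 0.35), with SAT levels near 0 in some libraries. The count of 555 genes fell to 309 or 310 without BAT DTR- replicate 2 or 4, to 327, 343 or 355 without BAT DTR+ replicate 2, 3 or 4. It was 324 without SAT DTR- replicate 4 and 335 without SAT DTR+ replicate 3.

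**Figure D1:**
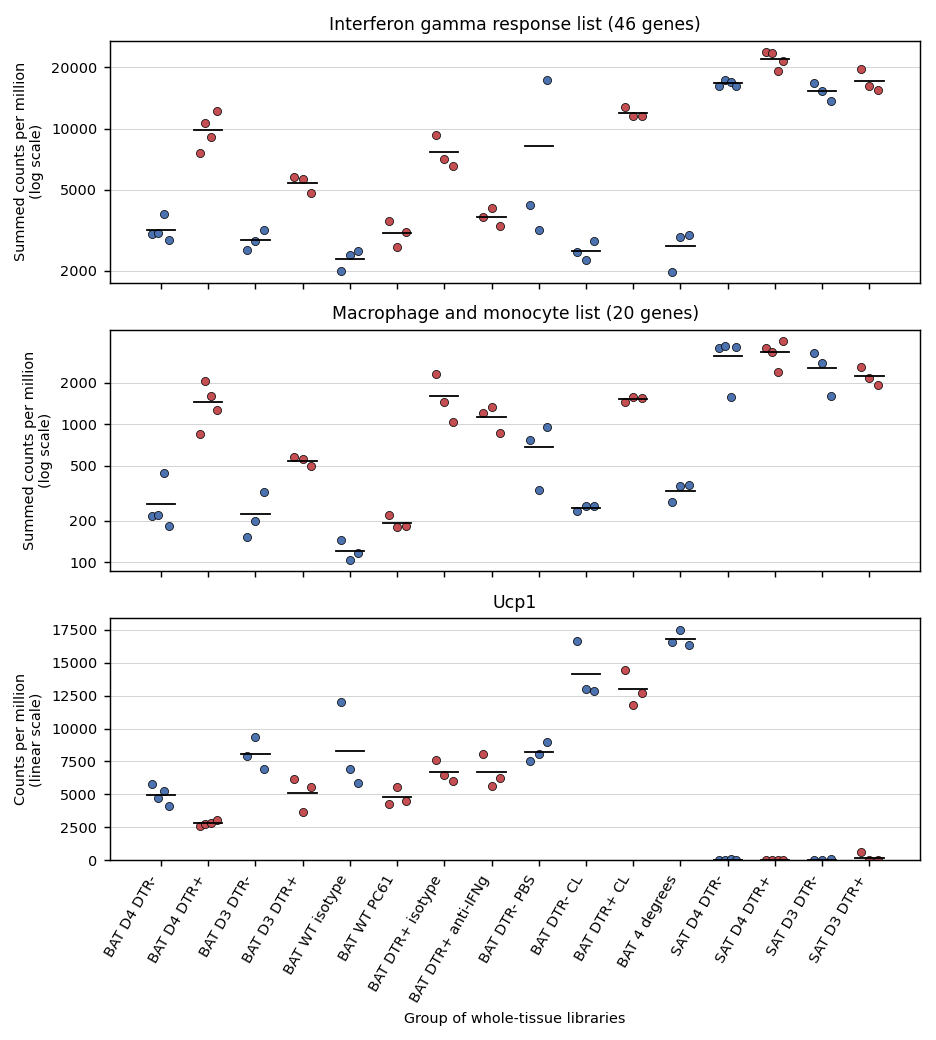
Each point is 1 whole-tissue library and each bar the mean of its group (3 or 4 libraries). The upper panels show summed CPM of the IFNg response and macrophage lists on log axes and the lowest panel Ucp1 CPM on a linear axis. In red are DTR+ libraries and those given PC61, and IFNg response sums in D4 BAT were 2843 to 3803 CPM in DTR- and 7565 to 12253 in DTR+ libraries, and DTR- PBS replicate 3 reached 17285.

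The D3 groups, whose titles add PBS, posed the same question in separate libraries. In D3 BAT 261 genes were higher and 150 lower in DTR+ of 11666 tested (n = 3 and 3; Foxp3 counts 2, 2 and 0 in DTR-, 0, 1 and 0 in DTR+). Ccl2 rose from 3.31 ± 1.91 to 44.6 ± 8.31 CPM (3.73 ± 0.33, adjusted p = 9.5e-05), with the chemokines Ccl7 (3.46 ± 0.38), Cxcl1 (4.82 ± 0.77) and Cxcl10 (2.66 ± 0.37). The circadian repressor Ciart also rose (3.79 ± 0.25). Ucp1 stood at 8744 ± 1495 CPM in DTR- and 4818 ± 1305 in DTR+ (-0.86 ± 0.23, adjusted p = 0.12), short of the threshold. IFNg response genes rose in 26 of 40 cases with 0 lower (33 and 0 adjusted over the list alone, mean 1.17, camera adjusted p = 6.3e-33 and 0.062 with an estimated correlation). Among them were Igtp (1.82 ± 0.13) and Irf1 (1.78 ± 0.14). Type I genes rose in 13 of 21 cases (19 adjusted over the list alone, mean 1.43, camera adjusted p = 4.2e-21 and 0.13 with an estimated correlation), including Rtp4 (2.29 ± 0.19). Macrophage genes also rose (4 of 19, 11 adjusted over the list alone, mean 1.23, camera adjusted p = 7.4e-10 and 0.20 with an estimated correlation), with Plac8 up by 2.58 ± 0.51. Immediate-early genes did so as well (3 of 18, 7 adjusted over the list alone, mean 1.42, camera adjusted p = 1.5e-11 and 0.062 with an estimated correlation), with Atf3 up by 2.44 ± 0.29, and so did cAMP response genes (1 of 12, Pde4b, also adjusted over the list alone, mean 0.85, camera adjusted p = 2.1e-05 and 0.37 with an estimated correlation).

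Lipid genes were lower in D3 BAT as well. Lipogenesis genes fell as a group (1 of 21, the malic enzyme Me1, by 1.58 ± 0.28, 8 adjusted over the list alone, mean -0.78, camera adjusted p = 1.2e-13 and 0.25 with an estimated correlation). Fatty acid oxidation genes fell (4 of 23, 15 adjusted over the list alone, mean -0.29, camera adjusted p = 8.0e-09 and 0.25 with an estimated correlation), Hadha by 0.54 ± 0.12, and oxidative phosphorylation genes (3 of 80, 25 adjusted over the list alone, mean -0.20, camera adjusted p = 7.6e-16 and 0.32 with an estimated correlation). Thermogenic genes fell as well (3 of 23, 6 adjusted over the list alone, mean -0.18, camera adjusted p = 0.0032 and 0.32 with an estimated correlation), Letmd1 by 0.70 ± 0.15 and Otop1 by 0.57 ± 0.15. The largest decreases also held Fam57b, by 2.11 ± 0.25, the pentose phosphate enzyme Tkt, by 1.26 ± 0.24, and the sterol enzyme Nsdhl, by 1.19 ± 0.18. Other lists rested on single libraries. Fibroblast genes (1 of 19 higher, Timp1, also adjusted over the list alone, mean 0.42, camera adjusted p = 0.0050 and 0.40 with an estimated correlation) lost their call without DTR- replicate 1 (0.075) or DTR+ replicate 2 (0.069). Muscle genes (0 of 14, mean 0.40, 0.018 and 0.60 with an estimated correlation) lost it without the same libraries (0.66, at a mean of -0.0046, and 0.23), and neutrophil genes (0 of 3, 2 adjusted over the list alone, mean 1.53, 0.020 and 0.25 with an estimated correlation) without DTR- replicate 2 (0.058). Cell-cycle genes (0 of 15, mean 0.61, 0.015 and 0.32 with an estimated correlation) lost it without DTR- replicate 3 (0.057) or DTR+ replicate 1 (0.085). Mitochondrially encoded genes (1 of 13 lower, mt-Nd1, 2 adjusted over the list alone, mean -0.16, 0.029 and 0.45 with an estimated correlation) lost it without DTR- replicate 1 (0.051) or 2 (0.11) or DTR+ replicate 1 (0.075) or 3 (0.087). The remaining lists did not move (camera adjusted p of 0.050 or more). Without DTR- replicate 1 the count of 411 genes fell to 258, and without DTR+ replicate 1 or 2 to 118 or 194.

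In D3 SAT no gene passed (0 of 12596 by edgeR, 629 at an unadjusted p under 0.05, 18 higher and 0 lower by DESeq2, 10 without DTR+ replicate 1). IFNg response genes were nonetheless higher as a group, with 28 of 45 past the threshold adjusted over the list alone (mean 0.56, camera adjusted p = 5.6e-27 and 0.29 with an estimated correlation). So were type I genes, with 14 of 23 adjusted over the list alone (mean 0.47, camera adjusted p = 6.4e-20 and 0.29 with an estimated correlation), though Bst2, at 0.59 ± 0.13, had an adjusted p of 0.39 over all genes. Camera also placed fibroblast genes lower (mean -0.29, adjusted p = 4.9e-07) and muscle (mean 1.33, 3.9e-06), Schwann cell (mean 0.48, 5.6e-06, 3 of 7 adjusted over the list alone), immediate-early (mean 0.34, 0.00071) and cAMP response genes (mean 0.51, 0.0014) higher. Each had an adjusted p of 0.29 to 0.48 with an estimated correlation, and single members such as Col3a1 (-0.63 ± 0.20) and Mbp (0.70 ± 0.17) did not pass. Endothelial genes (mean 0.26, 0.00062 and 0.43 with an estimated correlation) lost the call without DTR- replicate 1 (0.052). Lipogenesis genes (mean -0.14, 0.0070 and 0.66 with an estimated correlation) lost it and turned in sign without DTR- replicate 3 (mean 0.015, adjusted p = 0.39) or DTR+ replicate 1 (0.018 and 0.90). Oxidative phosphorylation genes (mean 0.09, 0.0019 and 0.82 with an estimated correlation) lost it without DTR- replicate 1 (0.16) or 2 (0.99) or DTR+ replicate 1 (0.54). The other lists did not move (camera adjusted p of 0.11 or more). Between the depots the D3 effect differed for 9 of 13325 genes, 8 with a larger and 1 with a lower change in BAT. Those with a larger change included Egr2 (3.49 ± 0.59), Ccl2 (3.06 ± 0.43) and Rtp4 (1.62 ± 0.23). This count was 4 to 5 without BAT DTR- replicate 2, BAT DTR+ replicate 1 or 2, SAT DTR- replicate 1 or SAT DTR+ replicate 2 or 3. It was larger without SAT DTR+ replicate 1 (14), BAT DTR+ replicate 3 (17), BAT DTR- replicate 3 (49) or SAT DTR- replicate 3 (63).

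Stimulation of BAT with CL was examined in DTR- mice. Of 12048 genes tested, 1967 were higher and 1423 lower with CL than with PBS (n = 3 and 3). Ucp1 rose from 8123 ± 1276 to 14582 ± 2363 CPM (0.84 ± 0.17, adjusted p = 0.0028). The coactivator Ppargc1a (chromosome 5, 51454250 to 51567726) went from 68.6 ± 14.0 to 2038 ± 475 CPM (4.89 ± 0.32, adjusted p = 6.1e-07). The thioesterase Acot5, in a cluster of close copies, went from 0.0560 ± 0.0969 to 149 ± 41.8 CPM (11.01 ± 0.47), the hormone Fgf21 rose by 6.94 ± 0.91 and the clock gene Arntl by 5.28 ± 0.39. The beta-3 receptor gene Adrb3 fell by 1.97 ± 0.20.

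The response covered signaling, substrate and stress genes. Of 12 cAMP response genes 8 rose (9 adjusted over the list alone, mean 2.45, camera adjusted p = 3.3e-08 and 0.46 with an estimated correlation). Examples were Nr4a3 (5.18 ± 0.32) and Pde4d (3.38 ± 0.22). Of 18 immediate-early genes 10 rose (11 adjusted over the list alone, mean 2.13, camera adjusted p = 1.0e-07 and 0.57 with an estimated correlation), such as Atf3 (4.66 ± 0.47) and Junb (2.84 ± 0.27). Thermogenic genes rose in 9 of 23 cases with 1 lower (10 and 3 adjusted over the list alone, mean 1.01, camera adjusted p = 0.018 and 0.57 with an estimated correlation), with Gmpr (3.78 ± 0.27) and Ppara (3.21 ± 0.28). Unfolded protein response genes rose in 7 of 14 cases with 2 lower (8 and 2 adjusted over the list alone, mean 1.18, camera adjusted p = 0.0076 and 0.57 with an estimated correlation). They included Atf4 (2.84 ± 0.21) and Gdf15 (4.22 ± 0.57). Endothelial genes rose in 6 of 12, the same adjusted over the list alone (mean 0.76, camera adjusted p = 0.013, but 0.054 without PBS replicate 3 and 0.57 with an estimated correlation), with Kdr (1.17 ± 0.21) and Cdh5 (2.05 ± 0.39). Lipogenesis genes fell in 8 of 21 cases with 1 higher, the same adjusted over the list alone (mean -0.57, camera adjusted p = 0.0076, but 0.056 without PBS replicate 2 and 0.57 with an estimated correlation). Srebf1 fell by 2.01 ± 0.21 and Acaca by 1.96 ± 0.23. Mitochondrially encoded genes fell in 4 of 13, the same adjusted over the list alone (mean -0.57, camera adjusted p = 0.020, but 0.054 without CL replicate 3, 0.067 without PBS replicate 2 and 0.57 with an estimated correlation; mt-Cytb, by 0.82 ± 0.21). Lipolysis genes moved in both directions (5 of 14 higher and 2 lower, 6 and 2 adjusted over the list alone, mean 0.58, camera adjusted p = 0.057). Fatty acid oxidation genes did as well (6 of 23 higher and 3 lower, also adjusted over the list alone, mean 0.24, median -0.03, camera adjusted p = 0.54). So did adipocyte genes (4 of 15 higher and 5 lower, also adjusted over the list alone, mean -0.13, camera adjusted p = 0.73). Oxidative phosphorylation genes did not move (mean -0.12, camera adjusted p = 0.057).

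Immune genes were lower with CL, a contrast shaped by 1 control. IFNg response genes summed to 4190, 3190 and 17285 CPM in PBS replicates 1 to 3 and to 2258 to 2792 CPM with CL. Of 46 such genes 13 fell and 1 rose (20 and 1 adjusted over the list alone, mean -2.09, or -0.40 without PBS replicate 3, camera adjusted p = 3.3e-06 and 0.57 with an estimated correlation), Irf8 by 2.74 ± 0.48 and Tapbp by 1.39 ± 0.29. Of 23 type I genes 6 fell, also adjusted over the list alone (mean -0.89, camera adjusted p = 0.011, but -0.55 and 0.062 without PBS replicate 3, and 0.60 with an estimated correlation), Usp18 by 1.64 ± 0.43. Of 20 macrophage genes 9 fell (12 adjusted over the list alone, mean -1.41, or -0.82 without PBS replicate 3, camera adjusted p = 0.00047 and 0.57 with an estimated correlation), Lyz2 by 1.82 ± 0.28 and Ctss by 2.53 ± 0.46. T and NK genes fell in 8 of 20 cases (10 adjusted over the list alone). Their mean was -3.75 and median -3.41, or -3.11 and -3.07 with 4 members undetected in a group at their bound (camera adjusted p = 0.0016 and 0.57 with an estimated correlation). Without PBS replicate 3 the mean was -1.19 (adjusted p = 0.13) with 1 gene called. Cell-cycle genes fell in 10 of 25 cases (11 adjusted over the list alone, mean -2.40, or -2.02 with 3 members at their bound and -1.5 without PBS replicate 3, camera adjusted p = 0.00040 and 0.57 with an estimated correlation), Mcm5 by 2.39 ± 0.53. With no count under CL, Gzmb was at least 29.8-fold lower, Aurkb 17.0-fold, Ccna2 16.1-fold, Cd8a 11.9-fold and Ncr1 11.7-fold. Gzmb stood at 0.504, 1.5 and 13.6 CPM in PBS replicates 1 to 3. Cd3g, Itgal, Trbc2 and Nkg7 fell by 4.43 to 5.30. Without PBS replicate 3 the decrease was 1.5 for Cd3g (adjusted p = 0.43), 2.45 for Trbc2 (0.13) and 2.08 for Nkg7 (0.053), and Cd8a (0.080) and Ncr1 (0.054) also no longer passed. Other lists did not move (camera adjusted p from 0.12 to 0.98). Without PBS replicate 3, 1596 genes were higher and 864 lower.

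Under CL, DTR+ BAT differed from DTR- BAT in 543 genes that were higher and 387 that were lower (n = 3 and 3). Ucp1 was close, 14582 ± 2363 CPM in DTR- and 12987 ± 1743 in DTR+ (-0.17 ± 0.17, adjusted p = 0.60). So was Ppargc1a (-0.38 ± 0.27, adjusted p = 0.42). Fatty acid synthase (Fasn, chromosome 11, 120805846 to 120824547) fell from 3507 ± 631 to 521 ± 207 CPM, by 2.75 ± 0.32 (adjusted p = 0.00089), and Acly from 1332 ± 228 to 220 ± 34.6 CPM, by 2.60 ± 0.30. Lipogenesis genes fell in 10 of 21 cases (12 adjusted over the list alone, mean -0.83, camera adjusted p = 1.9e-08 and 0.14 with an estimated correlation), Acaca by 1.65 ± 0.23. Thermogenic genes fell in 5 of 23 (9 adjusted over the list alone, mean -0.41, camera adjusted p = 1.9e-05 and 0.14 with an estimated correlation). They were led by Letmd1 (-0.89 ± 0.15), Otop1 (-0.98 ± 0.17), Adrb3 (-1.12 ± 0.20) and Ppara (-1.40 ± 0.26). Fatty acid oxidation genes fell in 5 of 23 cases (9 lower and 1 higher adjusted over the list alone, mean -0.34, camera adjusted p = 1.3e-05 and 0.24 with an estimated correlation), Ehhadh by 1.21 ± 0.24 and Acads by 1.04 ± 0.21. Oxidative phosphorylation genes shifted down as a group with 0 of 79 members called, also adjusted over the list alone (mean -0.24, camera adjusted p = 1.1e-07 and 0.48 with an estimated correlation).

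Immune genes were higher in DTR+ BAT under CL. Of 23 type I interferon genes 22 rose (23 adjusted over the list alone, mean 2.76, camera adjusted p = 2.7e-22 and 0.14 with an estimated correlation). Rsad2 (chromosome 12, 26442746 to 26456452) went from 21.6 ± 2.52 to 218 ± 94.7 CPM (3.33 ± 0.31), with Oasl2 (2.89 ± 0.38), Usp18 (3.14 ± 0.44) and Ifi44 (5.04 ± 0.70). IFNg response genes rose in 13 of 46 cases (42 adjusted over the list alone, mean 2.78, camera adjusted p = 4.6e-26 and 0.18 with an estimated correlation), with Cd274 (1.72 ± 0.25). Macrophage genes rose in 16 of 20 (18 adjusted over the list alone, mean 2.41, camera adjusted p = 1.2e-14 and 0.14 with an estimated correlation), with Lyz2 (2.98 ± 0.30). Cell-cycle genes rose in 10 of 25 (17 adjusted over the list alone, mean 3.06, or 2.69 with 3 members at their bound, camera adjusted p = 1.6e-12 and 0.18 with an estimated correlation), with Mcm5 (3.26 ± 0.54). T and NK genes rose in 5 of 20 (16 adjusted over the list alone, mean 4.17, or 3.55 with 4 members at their bound, camera adjusted p = 1.5e-10 and 0.23 with an estimated correlation), with Cd3d (4.63 ± 1.2). Mmp12 went from 0.462 ± 0.799 to 72.6 ± 14.4 CPM (6.70 ± 0.68). Genes without a count in DTR- rose at least 152-fold (Atp6v0d2), 46.0-fold (Gzmb) and 43.6-fold (Cd8b1). Matrix genes (6 of 20, 9 adjusted over the list alone, mean 0.74, camera adjusted p = 5.3e-05) also rose. Immediate-early genes did too (4 of 18, 5 adjusted over the list alone, mean 0.94, 0.0064). So did type 2 immune genes (1 of 3, 3 adjusted over the list alone, mean 2.01, 0.0045). Neutrophil genes did as well (1 of 3, 2 adjusted over the list alone, mean 2.03, 0.015). For these lists camera gave 0.24, 0.48, 0.14 and 0.14 with an estimated correlation. Their members included Dcn (1.05 ± 0.16), Timp1 (2.96 ± 0.55), Myc (2.17 ± 0.42), Ccl11 (1.90 ± 0.31) and S100a8 (2.34 ± 0.67). Other lists did not move (camera adjusted p of 0.058 or more), though Plin1 fell by 1.28 ± 0.24. The count of 930 was 499 or 418 without DTR- replicate 1 or 2 and 376 or 310 without DTR+ replicate 1 or 3. It was 1354 without PBS replicate 3, which is only in the fit.

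The antibody PC61 was given to wild-type mice, and BAT of these mice differed from isotype controls in 19 genes that were higher and 56 that were lower of 11513 tested (n = 3 and 3). Foxp3 had 0 counts in all 6 libraries, and Il2ra, the target chain, had 4 with isotype and 26 with PC61 (0.231 and 1.39 CPM), too few to test. Squalene epoxidase (Sqle, chromosome 15, 59315077 to 59331192) fell from 77.0 ± 18.1 to 27.1 ± 8.13 CPM, by 1.5 ± 0.22 (adjusted p = 0.0082), and Sc5d by 1.34 ± 0.12. Lipogenesis genes fell in 4 of 21 cases (9 adjusted over the list alone, mean -0.43, camera adjusted p = 1.4e-10 and 0.22 with an estimated correlation). Examples were Agpat2 (-0.90 ± 0.11), Lpin1 (-0.83 ± 0.12), Elovl6 (-0.65 ± 0.12) and the carbohydrate sensor Mlxipl (-0.75 ± 0.14). Other decreases were those of Hephl1, by 2.88 ± 0.36, the lipid droplet gene Plin2, by 0.92 ± 0.13, and Acot2, by 0.59 ± 0.12. Collagen genes rose, Col3a1 from 294 ± 60.5 to 572 ± 95.3 CPM (0.96 ± 0.16), Col1a1 by 0.72 ± 0.14 and Col1a2 by 0.69 ± 0.14. They were the 3 of 18 matrix genes that were called (11 adjusted over the list alone, mean 0.47, camera adjusted p = 2.2e-07 and 0.22 with an estimated correlation). Ucp1 did not pass (-0.89 ± 0.32, adjusted p = 0.42).

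Interferon response lists shifted up with PC61 at small effect sizes. Of 36 IFNg response genes 1 rose, Cd274 (0.64 ± 0.13, 6 adjusted over the list alone, mean 0.40, camera adjusted p = 5.2e-07 and 0.42 with an estimated correlation). Of 19 type I genes 0 rose, also adjusted over the list alone (mean 0.68, camera adjusted p = 5.5e-07 and 0.36 with an estimated correlation), with Rsad2 at 1.11 ± 0.33 (adjusted p = 0.24). Macrophage genes were higher as a group (0 of 15, mean 0.67, camera adjusted p = 0.00025 and 0.23 with an estimated correlation), and so were red cell genes (0 of 5, 3 adjusted over the list alone, mean 0.40, 0.0015, but 0.065 without isotype replicate 1 and 0.39 with an estimated correlation). Muscle genes (0 of 14, mean 2.16, 9.7e-07 and 0.42 with an estimated correlation) summed to 8290 CPM in PC61 replicate 2, without which their mean was -0.54. Small downward shifts lost their call when single libraries were left out. Thermogenic genes (0 of 22, mean -0.30, 0.023 and 0.56 with an estimated correlation) lost their call without isotype replicate 1 (0.84). Lipolysis genes (1 of 14, also adjusted over the list alone, mean -0.12, 0.047 and 0.39 with an estimated correlation) lost it without isotype replicate 1 (0.37) or 3 (0.086) or PC61 replicate 2 (0.10). Fatty acid oxidation genes (1 of 23, also adjusted over the list alone, mean -0.10, 0.014 and 0.56 with an estimated correlation) lost it without isotype replicate 1 (0.28) or PC61 replicate 1 (0.065) or 2 (0.10). Schwann cell genes (0 of 6, 1 adjusted over the list alone, mean -0.12, 0.025 and 0.32 with an estimated correlation) lost it without isotype replicate 1 (0.076) or 3 (0.057) or PC61 replicate 2 (0.22, with the mean turned to 0.049). The other lists did not move (camera adjusted p of 0.087 or more), and fewer than 3 T and NK genes were high enough to test. The count of 75 genes fell to 29 without isotype replicate 2 or 3, to 11 without PC61 replicate 1 and to 49 without PC61 replicate 3.

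IFNg was blocked in DTR+ BAT only, so return to DTR- levels is untested. With the antibody 61 genes were lower and 4 higher than with isotype of 12017 tested (n = 3 and 3). Iigp1 fell from 194 ± 24.8 to 20.9 ± 4.27 CPM, by 3.22 ± 0.16 (adjusted p = 2.6e-09). Gbp4 (chromosome 5, 105115767 to 105139586), whose reads may be shared with close copies, fell from 121 ± 21.7 to 18.7 ± 3.83 CPM, by 2.69 ± 0.19, Igtp by 2.20 ± 0.16 and Irgm2 by 2.03 ± 0.14. Of 42 IFNg response genes 26 fell and 0 rose (35 and 0 adjusted over the list alone, mean -1.38, camera adjusted p = 4.0e-72 and 0.066 with an estimated correlation). Of 23 type I genes 5 fell (18 adjusted over the list alone, mean -0.94, camera adjusted p = 7.5e-24 and 0.21 with an estimated correlation). Among them were Bst2 (-1.51 ± 0.15), Rsad2 (-1.15 ± 0.18), Rtp4 (-1.52 ± 0.25) and Isg15 (-1.32 ± 0.27). The largest decreases also held Zbp1 (-2.38 ± 0.35), Ifi47 (-2.37 ± 0.27) and Ifi209 (-2.87 ± 0.56). T and NK genes were lower as a group (0 of 12, 6 adjusted over the list alone, mean -1.24, camera adjusted p = 5.2e-08 and 0.21 with an estimated correlation). So were macrophage genes (1 of 20, Ly6c2, by 1.94 ± 0.42, 3 adjusted over the list alone, mean -0.55, camera adjusted p = 7.5e-06 and 0.57 with an estimated correlation).

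**Figure D2:**
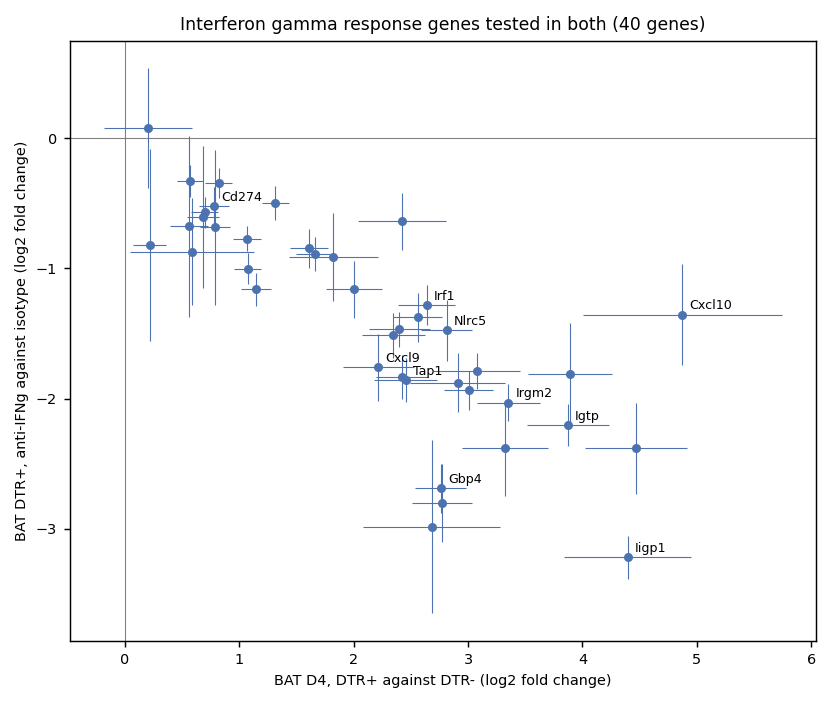
Each point is 1 of 40 IFNg response genes tested in both comparisons, placed by its log2 change in DTR+ D4 BAT and with the anti-IFNg antibody. Of these, 39 lay higher in the first and lower in the second, and 26 were called in both.

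Few metabolic genes passed with the antibody. Ucp1 stayed level (0.05 ± 0.12, adjusted p = 0.96), and the deiodinase Dio2 was the 1 of 24 thermogenic genes that moved, down by 1.01 ± 0.18 (also adjusted over the list alone, mean 0.02, camera adjusted p = 0.71). Lipogenesis genes were higher as a group (0 of 21, 1 adjusted over the list alone, mean 0.32, camera adjusted p = 8.4e-08 and 0.38 with an estimated correlation), with Scd1 at 0.46 ± 0.10 (adjusted p = 0.062). So were fatty acid oxidation genes (0 of 23, 1 adjusted over the list alone, mean 0.11, camera adjusted p = 0.00022 and 0.75 with an estimated correlation). The genes that rose were Echdc1 (0.81 ± 0.18), Rasd1 (0.80 ± 0.16), the glycogen regulator Ppp1r3b (0.74 ± 0.14) and Car3 (0.51 ± 0.10). Some lists rested on single libraries. Adipocyte genes (1 of 15, Car3, also adjusted over the list alone, mean 0.15, 0.016 and 0.75 with an estimated correlation) lost their call without anti-IFNg replicate 4 (0.16) or isotype replicate 3 (0.74). Muscle genes (0 of 14, mean 0.41, 0.0012 and 0.75 with an estimated correlation) lost it and turned in sign without anti-IFNg replicate 1 (mean -0.44, adjusted p = 0.082), and turned without isotype replicate 4 (mean -0.16). Red cell genes (0 of 5, mean -0.68, 0.0064 and 0.75 with an estimated correlation) lost it without anti-IFNg replicate 2 (0.061) or isotype replicate 8 (0.78), and mitochondrially encoded genes (0 of 13, mean -0.20, 0.012 and 0.75 with an estimated correlation) without anti-IFNg replicate 1 (0.24) or isotype replicate 4 (0.28). The other lists did not move (camera adjusted p of 0.12 or more). Without anti-IFNg replicate 4 or isotype replicate 3 the count of 65 genes was 41 or 40.

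Cold was examined last, in 3 BAT libraries from mice kept at 4 degrees. The labels give no control group for them, so they were set against the DTR- PBS libraries, which may come from another experiment and, unlike the cold libraries, carry a toxin label. Of 12329 genes tested 599 were higher and 469 lower than in these (n = 3 and 3). Ucp1 rose from 8417 ± 1203 to 16553 ± 820 CPM (0.98 ± 0.14, adjusted p = 0.0020). The creatine kinase Ckb (chromosome 12, 111669361 to 111672338) rose from 83.3 ± 18 to 1042 ± 291 CPM (3.65 ± 0.24, adjusted p = 8.1e-05), Bmp8b by 6.01 ± 0.78 and Acot5 by 6.93 ± 0.86. The complement factor Cfd fell by 2.32 ± 0.19 and adiponectin (Adipoq, chromosome 16, 23146536 to 23158028) from 2320 ± 247 to 847 ± 39.1 CPM, by 1.45 ± 0.13.

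Thermogenic genes rose in 7 of 24 cases with 2 lower (9 and 4 adjusted over the list alone, mean 0.84, camera adjusted p = 0.00056 and 0.60 with an estimated correlation). Endothelial genes rose in 7 of 12 (10 adjusted over the list alone, mean 1.02, camera adjusted p = 5.4e-08 and 0.60 with an estimated correlation), with Emcn (1.60 ± 0.21). Kdr rose by 1.12 ± 0.20 against these controls, but its change was -0.82 against the wild-type isotype group. Adipocyte genes fell in 6 of 15 cases with 1 higher (10 and 1 adjusted over the list alone, mean -0.70, camera adjusted p = 3.1e-05 and 0.18 with an estimated correlation). Lipid genes went both ways. Lpl (1.12 ± 0.17), Gpihbp1 (1.13 ± 0.15) and Plin2 (1.18 ± 0.18) rose, while Scd1 fell by 2.01 ± 0.25 and Pnpla2 by 0.96 ± 0.16. The lipogenesis list (4 of 21 higher and 3 lower, also adjusted over the list alone, mean 0.07, camera adjusted p = 0.87) and the lipolysis list (4 of 14 higher and 3 lower, 4 and 4 adjusted over the list alone, mean 0.07, camera adjusted p = 0.80) did not move. Scd2 (2.21 ± 0.24) and Agpat2 (0.87 ± 0.16) rose here but had changes of -0.74 and -0.05 against the D3 DTR- libraries, and the lipogenesis mean became -1.15. Fatty acid oxidation genes (1 of 23 higher and 5 lower, 1 and 6 adjusted over the list alone, mean -0.14, camera adjusted p = 0.020 and 0.81 with an estimated correlation) lost their call without cold replicate 2 (0.088). Cell-cycle genes (0 of 25, mean 0.70, camera adjusted p = 0.020 and 0.92 with an estimated correlation) lost theirs without PBS replicate 2 (0.50) or cold replicate 2 (0.47).

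Immune lists were lower in the cold libraries, but this depended on the control. IFNg response genes (2 of 41 lower, also adjusted over the list alone, Cd274 and Tapbp, mean -1.78, camera adjusted p = 1.1e-06 and 0.81 with an estimated correlation) had a mean of 0.23 against the wild-type isotype group. Type I genes (0 of 21, mean -1.04, camera adjusted p = 0.00054 and 0.81 with an estimated correlation) had means of 0.10 and 0.35 against the other controls. Macrophage genes (1 of 18 lower, Adgre1, 8 adjusted over the list alone, mean -1.22, camera adjusted p = 0.00018 and 0.81 with an estimated correlation) had means of 0.53 and 1.44. The other lists did not move (camera adjusted p of 0.097 or more). The count of 1068 genes was 621 without PBS replicate 1 and 610, 640 or 499 without cold replicate 1, 2 or 3. Against the D3 DTR- libraries it was 2724 and against the wild-type isotype libraries 2828.

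Genes called in D4 BAT, with CL against PBS and with the anti-IFNg antibody were then followed as sets in comparisons that share no library. Of 10 pairs of set and comparison for each, 9, 4 and 8 passed camera, and 0 did with an estimated correlation. Genes higher in D4 DTR+ BAT were also higher in D3 BAT (208 of 945 called, 0 lower, mean 0.78, camera adjusted p = 2.0e-52), under CL (327 of 1006 called, 8 lower, mean 1.32, 3.9e-34) and weakly with PC61 (7 of 811 called, 1 lower, mean 0.21, 1.1e-05). Each had 0.052 with an estimated correlation. Genes lower in D4 were lower in D3 (110 of 861, 0 higher, mean -0.38, 1.5e-55 and 0.085 with an estimated correlation) and with PC61 (32 of 861, 0 higher, mean -0.21, 2.2e-23 and 0.12 with an estimated correlation). They were also lower under CL (91 of 855, 3 higher, mean -0.32, 3.7e-14 and 0.15 with an estimated correlation). With the anti-IFNg antibody the first set fell (55 of 1005, 0 higher, mean -0.35, 6.0e-22 and 0.083 with an estimated correlation) and the second rose slightly (2 of 861, 0 lower, mean 0.15, 6.8e-15 and 0.16 with an estimated correlation). Of the genes that the antibody lowered, 55 of 60 were higher in D4 DTR+ BAT, 45 of 58 in D3 and 25 of 61 under CL, with 0 lower (means 2.29, 1.37 and 2.92, camera adjusted p of 7.4e-36 or less and 0.052 to 0.11 with an estimated correlation). With PC61 this set shifted up as a group (0 of 50, 9 adjusted over the list alone, mean 0.42, 2.8e-10 and 0.22 with an estimated correlation). The 4 genes that it raised passed downward in D4 BAT, under CL and in cold (means -0.46, -0.56 and -1.35, 0.11 to 0.16 with an estimated correlation). In cold the D4 set of higher genes (29 of 964 higher, 48 lower, mean -0.37, camera adjusted p = 0.034 and 0.61 with an estimated correlation) and the set lowered by the antibody (3 of 58 lower, mean -1.69, 3.0e-07 and 0.43 with an estimated correlation) were lower as a group, against controls that include PBS replicate 3. Genes lower in D4 went both ways there (96 higher, 68 lower, mean 0.04, adjusted p = 0.81). Genes higher with CL leaned up in D4 BAT (188 of 1879 higher, 59 lower, mean 0.18, camera adjusted p = 0.0012 and 0.11 with an estimated correlation) and D3 BAT (60 of 1884 higher, 15 lower, mean 0.16, 0.0012 and 0.19 with an estimated correlation). Those lower with CL went both ways in D4 BAT (174 of 1378 higher, 202 lower, mean 0.09, median -0.13, camera downward with 0.016 and 0.19 with an estimated correlation) and D3 BAT (55 of 1365 higher, 29 lower, mean 0.02, median -0.06, downward with 0.034 and 0.23 with an estimated correlation). The other 6 CL pairs did not pass.

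**Figure D3:**
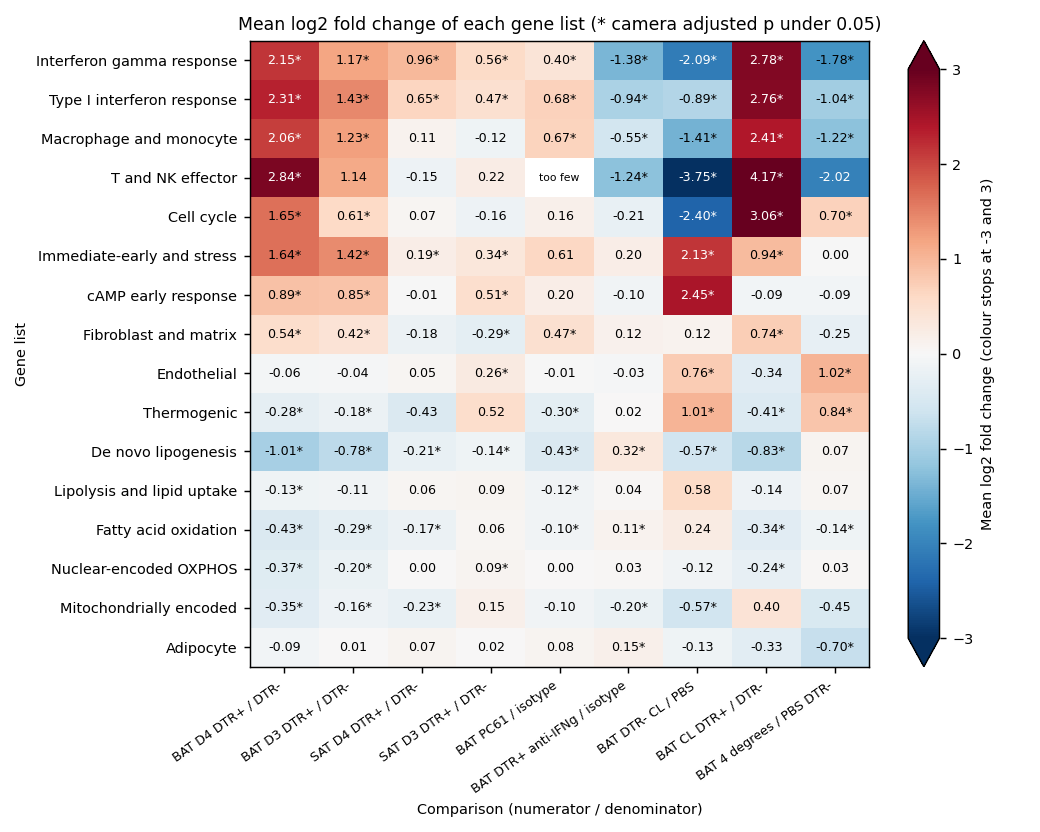
Mean log2 change of each gene list in each comparison, with an asterisk where camera gave an adjusted p under 0.05. Of 288 such tests 143 passed with the preset correlation and 4 with an estimated one.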

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

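The tests with single D3 libraries, of lymph node, of RNA from other cells, of processing time and of the D4 depot difference were chosen only after the result was seen.

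In groups of 4 libraries, 13 of 112 tested list sums had a library far from the others, by Dixon's test of the gap over the range at the 0.05 level, where chance gives about 1 in 20. In D4 BAT DTR- these were thermogenic (0.909, replicate 1) and neutrophil (0.859, replicate 1) and macrophage (0.851) and Schwann cell genes (0.911), both in replicate 3. In DTR+ they were muscle (0.937, replicate 1) and epithelial genes (1, replicate 3, 0.200 CPM against 0). In D4 SAT DTR- replicate 3 they were T and NK (0.920), Treg (0.892) and macrophage genes (0.941, 1575 against 3582 to 3708 CPM), and in replicate 4 epithelial genes (0.832). In DTR+ they were lipolysis (0.907) and muscle genes (0.976) in replicate 3 and neutrophil genes (0.924) in replicate 4.

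The DTR+ change differed between the depots when the difference itself was tested, for 555 genes at D4 and 9 at D3. At D4 camera placed these list means apart, BAT minus SAT: lipogenesis -0.82, lipolysis -0.22, fatty acid oxidation -0.22, IFNg 1.27, type I 1.61, T and NK 2.79, immediate-early 1.38, macrophage 2.00, fibroblast 0.68, adipocyte -0.19 (adjusted p = 0.029, lost without 1 of 5 libraries), red cell -0.61, cell cycle 1.93, cAMP 0.92 and oxidative phosphorylation -0.43. At D3 they were thermogenic -0.70, lipogenesis -0.66, lipolysis -0.22, fatty acid oxidation -0.37, IFNg 0.67, type I 0.98, T and NK 0.99, immediate-early 1.02, macrophage 1.33, endothelial -0.32, fibroblast 0.66, muscle -1.14, Schwann cell -0.96, cell cycle 0.70, cAMP 0.29, oxidative phosphorylation -0.32 and mitochondrially encoded -0.44. At D3 those for thermogenic, lipolysis, endothelial, muscle, cAMP and mitochondrially encoded genes were lost without single libraries, with thermogenic genes at 0.17 without SAT DTR+ replicate 1 and muscle genes at 0.055 without SAT DTR+ replicate 2. With an estimated correlation only the D4 cell-cycle list passed.

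Interferon and T cell genes stood high in BAT DTR- PBS replicate 3. A DTR+ library under a DTR- label would lower the 855 tested genes that fell in D4 DTR+ (median -0.49). Their median log2 ratio to replicates 1 and 2 was 0.10. Single D3 libraries against control pairs gave -0.41 to -0.23 (DTR+) and -0.13 to 0.19 (DTR-). Genes higher in D4, at 0.42, lay between D3 DTR+ (0.52 to 0.73) and DTR- (-0.18 to 0.17). So did Fasn, at -0.50 (-1.90 to -0.51 and -0.30 to 0.32). Genes that fell argue against such a label, and the others do not. Lymph node would bring B cells, but their list rose 1.17-fold against 11.5-fold for T and NK genes, which argues against it. The design gives no group for it, and no biological explanation was tested.

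Immediate-early genes stood higher in fat than in spleen Treg cells. The highest whole-fat sum in 20 libraries of DTR- and isotype controls was 0.147 of the lowest in fat Treg libraries (1107 against 7552 CPM). In all 52 tissue libraries it was 0.469 (3539 CPM). This argues against RNA of other fat cells unless processing raised their sum. Longer processing of fat cannot be told apart from a tissue difference: the lowest fat library was 4.97 times the highest spleen library, and tissue and processing coincide. A biological difference between the tissues stays open and was not tested.

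The D4 log2 change was larger in BAT than SAT, with an IFNg list mean of 2.15 against 0.96. A median SE ratio of 1.06 argues against wider SAT spread. The 671 genes without SAT DTR- replicate 3 argue against a control raised by it, though the T and NK mean was then 1.87. A higher base in SAT controls was not tested. Of 100 splits, 5 with the real one gave as many genes (555, highest other 1193). The 4 others kept the BAT groups and effect whole and decide nothing. A depot difference stays open.

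Splits made chance unlikely for Treg fat against spleen as 2 groups (1 of 56, real 1565, highest other 4). The same held for D4 BAT (1 of 35, 1882 and 0), not D4 SAT (2 of 35, 40 and 40). For the D3 interaction (9 of 100, 9 and 118) the 8 others again kept the BAT groups together and decide nothing. The 10 splits of 3 against 3 are too few for a share under 0.05. The real value and highest other were 411 and 0 in D3 BAT, 0 and 5 in D3 SAT, 3390 and 0 for CL, 930 and 0 for DTR+ under CL, 75 and 6 for PC61, 65 and 0 for anti-IFNg and 1068 and 0 for cold.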

How the results depend on the processing

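These settings were fixed before the data were examined, except for leaving out SAT D4 DTR- replicate 3 and DTR+ replicate 3 together, a test chosen only after the result was seen. Of 11808 values of named genes and called sets under another setting 10682 kept their direction and side of the threshold, 1028 no longer passed, 78 newly passed and 20 reversed. Of 3781 list values these were 3360, 247, 137 and 37. With RLE factors every count of genes stayed within 1.5 times its value.

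DESeq2 gave 90 genes for Treg BAT against SAT, 86 in D4 SAT, 949 for the D4 interaction, 18 in D3 SAT, 124 for the D3 interaction, 1526 for DTR+ under CL, 212 for PC61 and 99 for anti-IFNg. Without a filter on low counts the same 8 comparisons gave 136, 155, 887, 72, 273, 1552, 347 and 172, with 788 in D3 BAT and 1744 in cold. SAT Treg cells alone against spleen gave 1155 genes, D3 SAT in 1 fit of 4 groups 3, and D4 SAT without both named libraries 71. With an estimated correlation 4 of 288 list tests and 0 of 30 tests of called sets passed. A replicate block gave 1 gene for Treg BAT against SAT, 11 in D3 SAT, 5 for the D3 interaction and 658 in cold. Pairing by number is open: mean correlations of BAT and SAT residuals were -0.087 (D3 DTR-) to 0.093 (D3 DTR+). No cause was tested.

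With 1 library left out the counts ranged over 914 to 1862 for Treg fat against spleen, 0 to 14 for BAT against SAT, 1361 to 1879 in D4 BAT, 23 to 52 in D4 SAT, 309 to 679 for the D4 interaction, 118 to 391 in D3 BAT, 0 to 10 in D3 SAT, 4 to 63 for the D3 interaction, 2460 to 3428 for CL, 310 to 1354 for DTR+ under CL, 11 to 100 for PC61, 40 to 61 for anti-IFNg and 499 to 1046 in cold. List means reversed in sign or camera direction, given with their range: cell cycle in Treg BAT against SAT without BAT replicate 2 (-0.21, -0.21 to 0.69), and oxidative phosphorylation in D4 SAT without DTR- replicate 1 (-0.06) or DTR+ replicate 3 (-0.090, -0.090 to 0.056) and in D3 SAT without DTR- replicate 2 (0.014, 0.014 to 0.21). So did fatty acid oxidation in D3 SAT without DTR+ replicate 1 (-0.13, -0.13 to 0.26), and muscle in D4 SAT without DTR+ replicate 3 (-1.40, -1.40 to 3.44) or both named libraries (-1.52), in D3 BAT without DTR- replicate 1 (-0.0046, -0.0046 to 0.96) and in anti-IFNg without isotype replicate 4 or anti-IFNg replicate 1 (-0.16 and -0.44, -0.44 to 0.83). The same holds for muscle in D4 BAT without DTR+ replicate 1 (-2.76 to 1.12), in PC61 without PC61 replicate 2 (-0.54 to 7.65) and in the D3 interaction without SAT DTR+ replicate 2 (-4.70 to 0.055), and for thermogenic genes there without SAT DTR+ replicate 1 (-1.29 to 0.17). In D4 SAT T and NK genes (-0.28 to 0.77) and cAMP genes (-0.28 to 0.27) turned without DTR- replicate 3 and without both named libraries (0.79 and 0.40). Lipogenesis in D3 SAT turned without DTR- replicate 3 or DTR+ replicate 1 (0.015 and 0.018, from -0.38), and in PC61 Schwann cell genes without PC61 replicate 2 (-0.33 to 0.049) and oxidative phosphorylation without PC61 replicate 3 (-0.060 to 0.062). Without SAT replicate 1 immediate-early (-0.12 to 0.14) and mitochondrially encoded genes (-0.21 to 0.15) turned in Treg BAT against SAT, IFNg genes without BAT replicate 1 in Treg fat against spleen (-0.074 to 0.10), and immediate-early genes in cold without PBS replicate 3 (-0.31 to 0.81). Without the filter IFNg genes turned in Treg BAT against SAT (0.021) and T and NK genes in D4 SAT (0.051). With the top 100 genes the set lower with CL turned in D4 BAT (-0.21), D3 BAT (-0.084) and anti-IFNg (0.14). The cause was not tested.

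In cold, the D3 DTR- control gave 2724 genes and reversed Scd2 (-0.74), Agpat2 (-0.046), Fn1 (0.30), Cebpa (0.064), mt-Co2 (0.69) and the lipogenesis (-1.15), IFNg (0.035), type I (0.10) and macrophage (0.53) means. The wild-type isotype control gave 2828 and reversed Scd2 (-2.19), Agpat2 (-0.11), Ccl5 (2.17), Capg (2.01), Adgre1 (0.49), Ccl11 (1.11), Kdr (-0.82), Cebpa (0.60), Xbp1 (0.13), Pde3b (0.13), Uqcr11 (0.075), mt-Co2 (0.72) and the lipogenesis (-1.26), IFNg (0.23), type I (0.35), macrophage (1.44) and fibroblast (0.66) means. The cause was not tested. Depth limits Foxp3 in tissue, where many libraries had 0 counts.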

Other observations

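The lists here were chosen only after the result was seen, while the D4 and CL tests of cholesterol genes were fixed before theirs. Over 13 comparisons 32 of 52 such tests passed camera and 0 with an estimated correlation. Clock genes that peak with Arntl rose with CL (4 of 4, the same adjusted over the list alone, mean 3.31, camera adjusted p = 0.00015 and 0.208 with an estimated correlation). Their list also passed upward in cold (mean 1.61), the D3 interaction (0.68), anti-IFNg (0.42) and Treg fat against spleen (0.96) and BAT against SAT (0.46). Those that peak with Dbp rose in DTR+ D4 BAT (6 of 10, 9 adjusted over the list alone, mean 1.39, camera adjusted p = 2.5e-07 and 0.199 with an estimated correlation) and in D3 BAT (5 of 10, 7 adjusted over the list alone, mean 1.15, 4.5e-07 and 0.199 with an estimated correlation). They did not with DTR+ under CL (1 of 10, also adjusted over the list alone, mean 0.39, adjusted p = 0.37) or PC61 (0 of 8, mean -0.09, adjusted p = 0.45). Their list also passed upward in D4 SAT (0.35), D3 SAT (0.35), the D4 and D3 interactions (1.02 and 0.79) and Treg fat against spleen (1.09), and downward in cold (-0.92). Red pulp macrophage genes were lower in fat than in spleen Treg libraries (8 of 12, 9 adjusted over the list alone, mean -4.16, 1.1e-05 and 0.233 with an estimated correlation), but passed upward in D4 BAT (1.05), D3 BAT (0.54), DTR+ under CL (0.94) and the D4 and D3 interactions (1.26 and 0.94), and downward with anti-IFNg (-0.30).

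Cholesterol synthesis genes fell with PC61 (mean -0.70, 5 of 22, 14 adjusted over the list alone, camera adjusted p = 2.8e-15 and 0.199 with an estimated correlation). The hypothesis was that they may also be lower in DTR+ BAT. Their mean was -0.49 in D4 BAT (8 of 22 lower, also adjusted over the list alone, adjusted p = 0.00033 and 0.273 with an estimated correlation) and -0.36 for DTR+ under CL (0 of 22, 0.038 and 0.283), the direction the hypothesis needs, though neither passes with an estimated correlation. In D3 BAT the mean was -0.62, with anti-IFNg 0.30, and the list passed in 11 of 13 comparisons, upward in 4.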
